A study of Homo sapiens with 30 samples.

How the data were processed

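The values analysed are FPKM per gene and library, as deposited by the authors in 1 table per cell line with 48651 genes each. Per the submitters' processing notes, reads were aligned to hg19 with TopHat2 2.0.14 and Bowtie2 2.2.5, and FPKM came from Cufflinks and Cuffdiff 2.2.1. The gene annotation they used is not given in the sources used here. Per the labels, libraries were made from polyA RNA with the TruSeq RNA v2 kit after TRIzol and RNeasy extraction and sequenced as 76 bp paired-end reads. K562 cells grew in RPMI with serum and HUES9 cells in mTeSR1 on Geltrex, per the labels. Line, time point and replicate number came from the labels, and each of the 30 samples was matched to its column by these names. The tables also hold 3 per-replicate columns that match no sample, and these were not used.

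Gene symbols came from a table that pairs Ensembl identifiers with symbols and matched 45751 genes. Biotypes were matched by symbol from a RefSeq table of GRCh38.p14 and found for 33929 genes. No coordinate was used. Of the genes tested, 12222 of 13847 in K562 and 14291 of 15942 in HUES9 had a biotype, and genes without one (1625 and 1651) entered no class comparison.

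Levels were never compared between the tables, because each was likely normalised on its own, which the sources used here do not state. Genes with a mean of at least 0.5 FPKM over the 15 libraries of a line were tested. Values were transformed to log2(FPKM + 0.1) and fitted with limma 3.58.1 in R 4.3.3, with trend and robust empirical Bayes over all 15 libraries of the line. Each time point was contrasted with 0 h, and p-values were adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. An F-test over the 4 contrasts gave the genes with any change. FPKM have no counts behind them here, so a count model was not possible and the precision of low values is not modelled beyond the trend. The line difference was a contrast of changes over all 30 libraries for 12205 genes, after each line's median change was subtracted. Data preparation used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

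The 20 gene lists, the class comparison, the rule for named genes and the alternatives were fixed before the data were examined, except for 2 alternatives: centring on the median gene and the use of only K562 libraries 0 and 2. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data. The counts of members come from the gene-wise test adjusted over all genes, and were also made with p-values adjusted over the list alone. The lncRNA and mRNA classes were compared with camera, with an exact permutation test on the medians of the libraries, and with 10000 random mRNA lists matched to lncRNAs in 50 bins of mean expression. Camera compares gene-wise test statistics and not medians, so its direction can differ from the sign of a median difference. The named genes have a symbol, a mean of at least 5 FPKM over the line's 15 libraries, an adjusted p under 0.05 and no overlap between the groups. They are the 3 largest rises and falls at 0.5 h, the 6 largest each way at 2 h and 8 h, and the 5 largest each way for the line difference, where both lines needed that mean. The lncRNAs named are the 5 largest each way at 2 h with a mean of at least 2 FPKM, and lists name up to 4 members with the smallest p at 8 h. Globins, GAPDH, ACTB, MYC, FOS, POU5F1, NANOG, GATA1 and MALAT1 were reference genes. Some results of genes that these rules select are not reported here.

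Libraries with the same replicate number resembled each other across time points. After removal of group means, the 30 same-number pairs of a line had a median correlation of 0.351 in K562 and 0.344 in HUES9 and a lowest one of 0.177 and 0.124, against medians of −0.309 and −0.157 for different numbers. The number therefore pairs libraries, and the fit with the number as a block is given beside a result where it changes a call or moves a count by more than 1.5 times.

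Each library was also rescaled in 3 ways: to the same sum (TPM), by quantiles, and to the median of the ribosomal protein mRNAs. Quantile normalisation gives every library the same values rank by rank, so highly expressed transcripts have little room to rise under it. The method was tried on simulated libraries, with known changes added to 200 genes. Their values were drawn as independent normal noise around each gene's 0 h mean, with its fitted spread. Unlike the real libraries, they held no pairing by replicate number and few changed genes. In the K562 contrast at 2 h, 55.2%, 82.1% and 97.0% of 1.5-, 2- and 4-fold changes were found, and in HUES9 59.7%, 91.0% and 98.5%. For the line difference these shares were 47.8%, 85.1% and 97.0% at 2 h and 44.8%, 77.6% and 98.5% at 8 h. False calls made up 2.34% to 10.5% of calls over all contrasts of the simulated libraries, and these shares need not hold for the real ones.

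The depth of the libraries is unknown, and no number of fragments can be read from FPKM. Between libraries, shared steps in low values put the worth of 1 fragment in K562 replicate 1 at 1.44 times that of K562 0 h replicate 0 at 0 h and 2.77 times at 8 h. Whole fragments were not recovered, so these ratios are rough. The share of FPKM in mitochondrial genes fell from 9.67% to 6.92% in K562 and from 10.4% to 8.83% in HUES9 between 0 h and 8 h, while that of mitochondrial ribosomal RNA rose from 0.49% to 1.70% and from 0.58% to 2.42%.

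Absolute half-lives were not calculated, since no spike-in is described and the values are relative.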

Results

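Transcript levels were measured by RNA sequencing of polyA-selected libraries from K562, a human erythroleukaemia line, and HUES9, a human embryonic stem cell line grown without feeder cells. Both lines were treated with actinomycin D at 5 µg/ml, a drug that binds DNA and blocks transcription, and RNA was collected at 0, 0.5, 2, 4 and 8 h. Each line and time point had 3 libraries, 30 in all. The series title sets long noncoding RNAs (lncRNAs) against mRNAs, and the design asks which transcripts of each class are lost faster or slower than the rest once transcription stops. The deposited values are FPKM, fragment counts normalised to transcript length and to the size of the library, with 1 value per gene and library, from separate tables for the lines. Levels were therefore compared only within a line. How the authors set the size of each library is not known here. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Replicates had Pearson's r of 0.9845 to 0.9937 across genes, and no pair of libraries held identical values. The number of fragments per library is unknown.

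FPKM values are relative to the RNA that remains, and this scale sets the direction of many changes. The sum of FPKM over all genes rose from 596293 ± 5429 at 0 h to 1074648 ± 34197 (SD, n = 3) at 8 h in K562, and from 611839 ± 9325 to 844404 ± 27454 (SD, n = 3) in HUES9. On the deposited scale the median gene changed little, by 0.10 at 2 h and 0.07 at 8 h in K562 and by 0.06 and −0.01 in HUES9 (log2). The authors' library scaling may itself hold the median gene level, so this does not show that its RNA was unchanged. With each library rescaled to the same sum (TPM), the median gene changed by −0.75 in K562 and −0.46 in HUES9 at 8 h. When the ribosomal protein mRNAs were held level instead, the median gene changed by −0.47 at 2 h and −1.25 at 8 h in K562, and by −0.29 and −0.73 in HUES9. Single genes are given below on the deposited scale, and under ribosomal protein scaling any rise smaller than that of the ribosomal protein mRNAs becomes a fall. Changes of gene lists are given relative to the median gene of the line. All changes are differences of mean log2(FPKM + 0.1), which understates the change of low genes, and ± after a log2 change is its standard error.

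After 0.5 h in K562 the fit without the replicate number called a small set of transcripts, most of them lower. The fit with that number as a block called many more, with more rises than falls. MYC, the proto-oncogenic transcription factor (ENSG00000136997.10), fell from 104 ± 7.12 to 35.6 ± 11.6 FPKM (SD, n = 3), a log2 change of −1.59 ± 0.17 (limma, adjusted p = 0.00106). CISH, a cytokine-induced inhibitor of STAT5 signalling (ENSG00000114737.11), fell by 1.76 ± 0.25 on the log2 scale, and TGIF1, a repressor of TGF-beta signalling, fell by 1.19 ± 0.14. The largest rises among genes of at least 5 FPKM were those of C4orf48 (0.67 ± 0.13), the mitochondrially encoded MT-CO2 (0.48 ± 0.05, 0.00 under quantile normalisation) and BTNL9 (0.44 ± 0.08). In all, 12 of 13847 genes were higher and 57 lower (limma, adjusted p under 0.05), while 1474 had an unadjusted p under 0.05. The split was 9 higher and 235 lower under TPM scaling and 6 and 545 under ribosomal protein scaling. With the replicate number as a block, 1297 genes were higher and 650 lower. Leaving out any single library left 2 to 5 higher and 11 to 20 lower genes. C4orf48 and BTNL9 lost the call without any 1 of the 6 libraries, BTNL9 also under TPM and ribosomal protein scaling, and CISH without library 2 of 0 h. A fit of only the 6 libraries compared left 3 higher and 30 lower genes, and C4orf48 (adjusted p = 0.122), BTNL9 (0.0574) and CISH (0.0645) lost the call.

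By 2 h, transcripts of K562 regulators had fallen to a small part of their starting level. CISH fell from 22.3 ± 5.03 to 0.602 ± 0.0964 FPKM (log2 change −4.98 ± 0.25, 31.5-fold lower) and MYC to 5.51 ± 0.914 FPKM (−4.22 ± 0.17, 18.7-fold lower; SD, n = 3). The stress-induced mTOR inhibitor DDIT4 fell by 3.83 ± 0.50 on the log2 scale, although its 0 h libraries were spread widely, at 29.8 ± 23.2 FPKM (SD, n = 3). CITED2, a CBP/p300-binding transcriptional regulator (−3.70 ± 0.14), ID1, an inhibitor of helix-loop-helix factors (−3.17 ± 0.19), and FBXO5, which encodes the APC/C inhibitor EMI1 (−3.14 ± 0.18), also fell. Among genes of at least 5 FPKM, the largest rises were those of RNAs other than mRNAs: the small Cajal body RNA SCARNA9 (2.63 ± 0.26) and the mitochondrial ribosomal RNAs MT-RNR1 (2.22 ± 0.14, from 437 ± 105 to 1990 ± 73.9 FPKM) and MT-RNR2 (1.57 ± 0.12). AMH, anti-Müllerian hormone (1.34 ± 0.41), ANO9 (1.29 ± 0.20) and PGGHG (1.29 ± 0.28) followed. AMH lost its call without library 1 of 0 h or library 0 of 2 h and under TPM and ribosomal protein scaling, and PGGHG under ribosomal protein scaling.

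Among the gene lists in K562 at 2 h, immediate early and other short-lived regulators had a median change of −2.14 relative to the median gene, with 28 of 32 lower and none higher (camera, adjusted p = 1.37e-17). NF-kB target genes fell by 1.2, with 10 of 13 lower (2.05e-05), and zinc finger genes with a ZNF number fell by 0.75, with 249 of 374 lower and 13 higher (9.30e-21). Ribosomal protein mRNAs rose by 0.49, with 76 of 77 higher (5.28e-29), and nuclear-encoded oxidative phosphorylation mRNAs by 0.45, with 62 of 63 higher (1.31e-20). Under quantile normalisation the ribosomal protein change was −0.02, and that of oxidative phosphorylation mRNAs was 0.06. These 5 calls held with an estimated correlation. Glycolytic enzyme mRNAs rose by 0.35, with 14 of 17 higher and 1 lower (0.00013), but changed by −0.03 under quantile normalisation; the adjusted p was 0.203 with an estimated correlation. p53 target genes fell by 0.35, with 9 of 20 lower and 3 higher (0.0314; adjusted p = 0.0774 with an estimated correlation). Genes of the integrated stress and unfolded protein responses fell by 0.82, with 9 of 16 lower and 3 higher (0.00819; adjusted p = 0.12 with an estimated correlation). Replication-dependent histone mRNAs rose by 0.19, with 13 of 25 higher and 2 lower (0.0288; adjusted p = 0.419 with an estimated correlation and 0.0833 with the replicate block, 0.000992 to 0.419 over all alternatives). The histone values cover only RNA that came through the polyA selection. Adjusted over the list alone, the lower counts were 28, 10, 255, 9 and 9 for the regulators, NF-kB targets, zinc finger genes, p53 targets and stress genes. The higher counts were 76, 63, 15 and 13 for ribosomal proteins, oxidative phosphorylation, glycolysis and histones. Erythroid genes did not pass as a list (adjusted p = 0.213): 10 of 26 were higher and 4 lower. HBE1 (0.57 ± 0.05) and HBG2 (0.60 ± 0.06) rose, but changed by 0.07 each under quantile normalisation and by −0.02 and 0.01 under ribosomal protein scaling. The globin paralogs HBA1 (0.43 ± 0.30) and HBA2 (0.46 ± 0.27), which share reads, missed the threshold (adjusted p = 0.253 and 0.178) but passed with the replicate block (0.0204 and 1.25e-05). The DNA replication (camera, adjusted p = 0.0505), mitochondrially encoded, pluripotency, germ layer, myeloid, mitotic, snoRNA host, well-known lncRNA, heat shock and cholesterol lists did not pass. The snoRNA host list also holds other transcripts sensitive to nonsense-mediated decay. Over all genes 3707 were higher and 2987 lower at 2 h, 117 and 1033 of them by at least 2-fold. TPM scaling gave 529 higher and 5803 lower, and ribosomal protein scaling 63 and 9023.

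At 8 h in K562, CISH and MYC remained among the 6 largest falls of genes of at least 5 FPKM, at 0.335 ± 0.0645 and 3.35 ± 0.258 FPKM (SD, n = 3; log2 changes −5.67 ± 0.25 and −4.91 ± 0.17). DDIT4 (−4.60 ± 0.50), the mRNA export cofactor NXT1 (−4.37 ± 0.20), the HSP40 co-chaperone DNAJB1 (−4.16 ± 0.19) and the autophagy factor ATG101 (−4.02 ± 0.16) completed that set. The small nucleolar RNA SNORD3A rose from 5.6 ± 1.28 to 200 ± 271 FPKM (4.16 ± 1.00) and the RNA polymerase II regulator 7SK from 3.92 ± 1.36 to 117 ± 156 FPKM (3.96 ± 0.95), with a wide spread between the 8 h libraries. SCARNA9 (4.10 ± 0.26), MT-RNR1 (3.42 ± 0.14), C4orf48 (2.65 ± 0.13) and CFD, complement factor D (2.55 ± 0.15), also rose. The erythroid transcription factors KLF1 (−3.35 ± 0.18), TAL1 (−1.81 ± 0.09) and GATA1 (−1.22 ± 0.32) fell, while the embryonic and fetal globins HBE1 (1.42 ± 0.05), HBG2 (1.46 ± 0.06), HBZ (1.49 ± 0.17) and HBG1 (1.36 ± 0.08) rose. In the erythroid list, which did not pass as a whole (camera, adjusted p = 0.126), 16 of 26 genes were higher and 9 lower. GAPDH rose by 1.42 ± 0.11, but changed by 0.09 under quantile normalisation and 0.05 under ribosomal protein scaling. Under ribosomal protein scaling none of these 4 globins passed (changes −0.01 to 0.13), and HBG1 did not pass under quantile normalisation (0.06).

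In the K562 lists at 8 h, immediate early and short-lived regulators had a median of −2.25 relative to the median gene, with 31 of 32 lower, among them HES1 (−3.74 ± 0.18) and PIM1 (−2.47 ± 0.14) (camera, adjusted p = 8.15e-09; adjusted p = 0.153 with an estimated correlation). Ribosomal protein mRNAs rose by 1.39, with 76 of 77 higher, for example RPS12 from 2300 ± 34.7 to 7160 ± 248 FPKM (2.19e-26; adjusted p = 0.0718 with an estimated correlation), although quantile normalisation left 0.02. Oxidative phosphorylation mRNAs rose by 1.30, with 62 of 63 higher and 1 lower (7.57e-20), as did glycolytic enzyme mRNAs by 1.18, with 14 of 17 higher and 2 lower (0.000226; adjusted p = 0.205 with an estimated correlation); quantile normalisation left 0.28 and 0.09. Among the mitochondrially encoded mRNAs, which did not pass as a list (adjusted p = 0.273), 6 of 13 were lower, such as MT-ND3 (−2.56 ± 0.08), and 3 higher, such as MT-CO1 (0.78 ± 0.04, but −0.07, −0.40 and −0.59 under TPM, quantile and ribosomal protein scaling). NF-kB targets fell by 1.58, with 11 of 13 lower, such as NFKBIA (−4.08 ± 0.28) (0.00125; adjusted p = 0.0718 with an estimated correlation). Stress response genes fell by 1.95, with 11 of 16 lower and 5 higher, and XBP1 fell from 45.9 ± 1.83 to 2.85 ± 0.294 FPKM (0.0336; adjusted p = 0.205 with an estimated correlation and 0.0516 with the replicate block, 0.00256 to 0.257 over all alternatives). p53 targets fell by 0.95, with 13 of 20 lower, such as PPM1D (−3.82 ± 0.19), and 3 higher (0.0291; adjusted p = 0.0883 with an estimated correlation). Mitotic genes fell by 0.74, with 16 of 27 lower, such as AURKA (−3.40 ± 0.11), and 4 higher (0.00535; adjusted p = 0.479 with an estimated correlation). Zinc finger genes fell by 0.84, with 263 of 374 lower, such as ZNF622 (−3.29 ± 0.10), and 44 higher (3.79e-09). The calls for oxidative phosphorylation and zinc finger genes held with an estimated correlation. Histone mRNAs, a family whose copies share reads, rose by 0.74, with 18 of 25 higher and 3 lower (0.00247; adjusted p = 0.205 with an estimated correlation). Of the well-known lncRNAs, 12 of 17 were higher, such as PVT1 (1.11 ± 0.07, −0.26 under ribosomal protein scaling), and 2 lower, NORAD (−2.38 ± 0.11) and MIR17HG (−3.86 ± 0.18); the list rose by 0.70 (0.036; adjusted p = 0.392 with an estimated correlation), and the call was lost without library 1 of 8 h (0.79), under quantile normalisation (0.38; adjusted p = 0.127) and with the filter at a mean of 2 FPKM (0.83; adjusted p = 0.0615). Adjusted over the list alone the counts were the same for these lists except zinc finger genes, with 264 lower and 46 higher. The histone values again cover only RNA that came through the polyA selection. DNA replication, heat shock, cholesterol, snoRNA host, myeloid, germ layer, erythroid and pluripotency lists did not pass (adjusted p = 0.126 to 0.964). At 4 h and 8 h, 4848 and 5453 genes were higher and 4197 and 5120 lower. TPM scaling gave 996 and 1299 higher with 7522 and 9051 lower, and ribosomal protein scaling 101 and 134 higher with 10115 and 11622 lower.

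**Figure D1:**
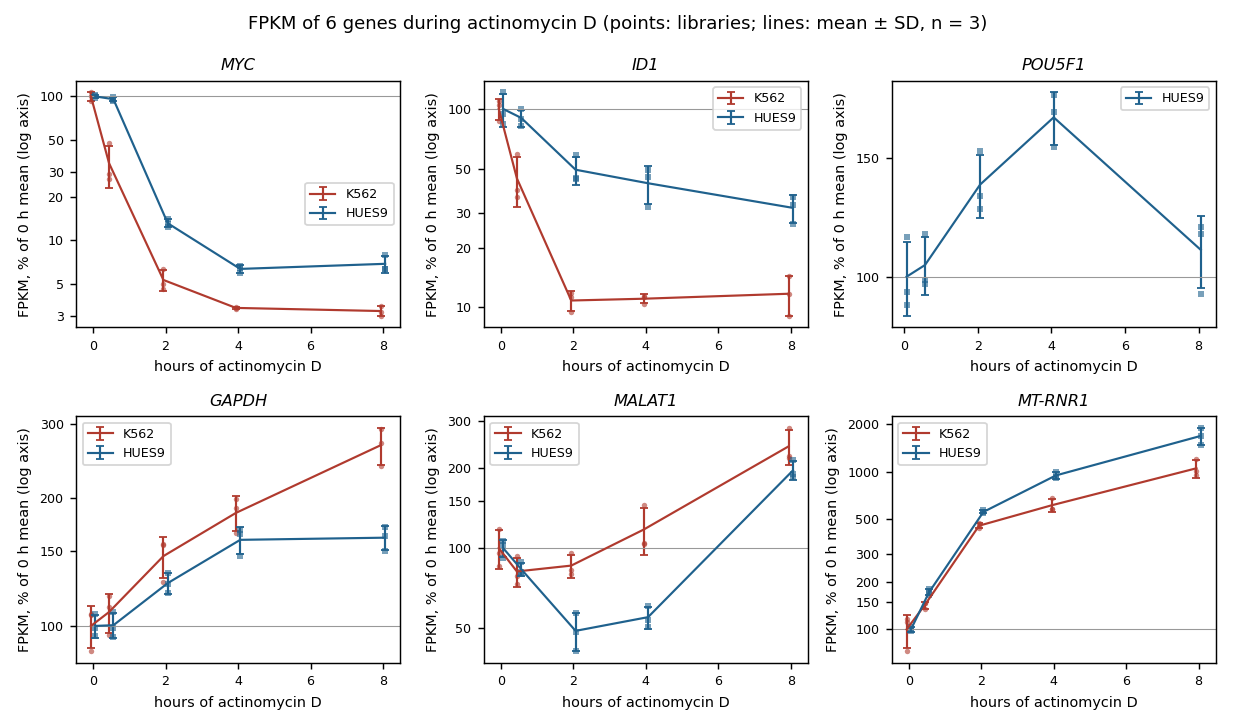
FPKM of MYC, ID1, POU5F1 (HUES9 only), GAPDH, MALAT1 and MT-RNR1 as a percentage of the 0 h mean, on a logarithmic axis, against hours of actinomycin D; points are libraries, lines and bars the mean ± SD (n = 3). MYC and ID1 fall and MT-RNR1 rises in both lines; the rise of GAPDH at 8 h becomes 0.09 in K562 and −0.14 in HUES9 under quantile normalisation and 0.05 and −0.06 under ribosomal protein scaling, that of MALAT1 in K562 −0.09 under ribosomal protein scaling, and POU5F1 at 8 h changes from 0.13 to −0.33 with TPM, −0.53 with quantile and −0.62 with ribosomal protein scaling (log2).

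HUES9 cells showed few changes at 0.5 h. SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell from 15.3 ± 0.97 to 8.80 ± 0.979 FPKM (SD, n = 3; log2 change −0.80 ± 0.13, limma adjusted p = 0.0172). The snoRNA host SNHG12 fell by 0.58 ± 0.10 and the cyclin CCNL1 by 0.43 ± 0.08. MT-RNR1 (0.78 ± 0.07), AMH (1.2 ± 0.16) and the atypical MAP kinase MAPK15 (1.05 ± 0.12) rose. In all 15 of 15942 genes were higher and 14 lower, with 848 at an unadjusted p under 0.05, and 51 higher and 38 lower with the replicate block. Leaving out single libraries left 4 to 13 higher and 0 to 4 lower genes. The calls of SNHG12 and CCNL1 were lost without any 1 of the 6 libraries and that of SPRY1 without 4 of them. In a fit of only the 6 libraries compared, which left 1 higher and 3 lower genes, AMH (adjusted p = 0.0641), MAPK15 (0.0988), SPRY1 (0.0512), SNHG12 (0.0754) and CCNL1 (0.147) lost the call and MT-RNR1 kept it.

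At 2 h in HUES9 the receptor tyrosine kinase signalling inhibitors SPRY1 (−4.0 ± 0.13, 15.3 ± 0.97 to 0.872 ± 0.162 FPKM) and SPRY2 (−3.36 ± 0.14) fell, as did the vasodilator peptide gene ADM (−3.99 ± 0.12), RASL11B (−3.97 ± 0.14) and the pseudokinase gene TRIB1 (−3.89 ± 0.12; n = 3 libraries per group throughout). MYC fell from 26.2 ± 0.575 to 3.45 ± 0.219 FPKM (−2.89 ± 0.09). Among genes of at least 5 FPKM, MT-RNR1 rose from 511 ± 15.7 to 2850 ± 63.3 FPKM (2.48 ± 0.07), followed by AMH (2.15 ± 0.16), the endonuclease subunit EME2 (2.13 ± 0.19), MAPK15 (2.13 ± 0.12), PTOV1-AS2 (1.48 ± 0.10) and LY6G5B (1.46 ± 0.08). POU5F1, which encodes the pluripotency factor OCT4, rose by 0.45 ± 0.11 (0.23 under TPM scaling, 0.17 under quantile normalisation and 0.09 under ribosomal protein scaling, none past the test), whereas NANOG fell by 0.67 ± 0.06. Immediate early and short-lived regulators had a median of −2.36 relative to the median gene, with 32 of 34 lower (camera, adjusted p = 4.73e-26). Zinc finger genes fell by 0.79, with 292 of 412 lower and 8 higher (1.35e-29), and stress response genes by 0.86, with 11 of 17 lower and 5 higher (0.000556). These 3 calls held with an estimated correlation, and the next 5 did not. Ribosomal protein mRNAs rose by 0.30, with 75 of 77 higher (1.34e-24; adjusted p = 0.0968 with an estimated correlation), but changed by −0.04 under quantile normalisation. Oxidative phosphorylation mRNAs rose by 0.25, with 52 of 63 higher (6.60e-14; 0.0968), but changed by 0.00 under quantile normalisation. Glycolytic mRNAs rose by 0.27, with 16 of 17 higher (1.30e-05; 0.0968), but changed by −0.04 under quantile normalisation. p53 targets fell by 0.50, with 12 of 25 lower and 3 higher (0.000498; 0.0873), and NF-kB targets by 0.58, with 7 of 14 lower (0.00542; 0.0968), but by 0.20, not past the test, with the filter at a mean of 2 FPKM (adjusted p = 0.0532). Adjusted over the list alone, the lower counts were 32, 300, 11, 12 and 7 for regulators, zinc finger genes, stress genes, p53 targets and NF-kB targets, and the higher counts 76, 53 and 16 for ribosomal proteins, oxidative phosphorylation and glycolysis. No other list passed (adjusted p = 0.0778 to 0.986). Over all genes 3592 were higher and 3415 lower, 108 and 1063 of them by at least 2-fold. TPM scaling gave 702 higher and 5581 lower, and ribosomal protein scaling 229 and 7860.

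Pluripotency regulators were low by 8 h in HUES9. NANOG fell from 53.1 ± 2.78 to 5.17 ± 0.272 FPKM (SD, n = 3; −3.33 ± 0.06), SOX2 by 2.69 ± 0.07 and ZFP42 by 3.02 ± 0.09, whereas POU5F1 stood at 1010 ± 122 FPKM against 918 ± 115 at 0 h (0.13 ± 0.11, adjusted p = 0.293). POU5F1 passed as a rise with the replicate block (adjusted p = 0.0301) and with each library centred on its median gene (0.000587). It passed as a fall under TPM (−0.33, adjusted p = 0.00857), quantile (−0.53, 0.000127) and ribosomal protein scaling (−0.62, 2.48e-05), so its direction depends on the scaling. Of the pluripotency list, 16 of 21 were lower and 1 higher, with a median of −1.62 relative to the median gene (camera, adjusted p = 0.000239). The 6 largest falls among genes of at least 5 FPKM were those of CHAC1, a glutathione-degrading enzyme of the stress response (−5.57 ± 0.14), TENT5B (−5.18 ± 0.14), the planar polarity gene PRICKLE1 (−4.55 ± 0.12), the SMN complex helicase DDX20 (−4.38 ± 0.11), RASL11B (−4.38 ± 0.14) and the mesendoderm factor MIXL1 (−4.34 ± 0.37). The largest rises among these genes were those of 7SK (4.47 ± 0.17), SNORD3A (4.36 ± 0.18), MT-RNR1 (4.07 ± 0.07), MAPK15 (4.04 ± 0.12), the cystatin CST1 (3.72 ± 0.58, from 18.5 ± 16.2 to 195 ± 48.4 FPKM) and the atrial myosin light chain MYL4 (3.72 ± 0.32). In the list of differentiated germ layer genes, which did not pass as a whole (adjusted p = 0.66), 5 of 12 were higher, including smooth muscle actin ACTA2 (3.57 ± 0.23) and the collagens COL3A1 (3.39 ± 0.24) and COL1A1 (2.92 ± 0.22), and 5 were lower, including MIXL1.

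Among the other lists at 8 h in HUES9, immediate early and short-lived regulators had a median of −2.30, with 33 of 34 lower, for example MCL1 (−2.55 ± 0.06) and DUSP5 (−4.51 ± 0.12) (camera, adjusted p = 4.54e-10; adjusted p = 0.178 with an estimated correlation). Zinc finger genes fell by 0.93, with 298 of 412 lower, such as ZNF281 (−3.66 ± 0.07), and 40 higher (4.59e-10). The zinc finger and pluripotency calls held with an estimated correlation, and those of the following 6 lists did not. Ribosomal protein mRNAs rose by 0.84, with 76 of 77 higher, such as RPLP2 (1.1 ± 0.04) (1.70e-19; 0.237), and 0.02 remained under quantile normalisation. Oxidative phosphorylation mRNAs rose by 0.67, with 50 of 63 higher and 7 lower (2.31e-07; 0.251), and 0.02 remained under quantile normalisation. Glycolytic mRNAs rose by 0.69, with 13 of 17 higher, such as PKM (2.03 ± 0.07), and 3 lower, such as HK2 (−1.86 ± 0.09) (0.00495; 0.251), but the list changed by −0.07 under quantile normalisation. Mitotic genes fell by 0.72, with 21 of 28 lower, such as CCNB1 (−2.46 ± 0.05), and 2 higher (0.000239; 0.251). DNA replication genes fell by 0.54, with 18 of 30 lower, such as FEN1 (−2.07 ± 0.06), and 6 higher (0.0213; 0.517). Mitochondrially encoded mRNAs fell by 0.23, with 8 of 13 lower, such as MT-ND5 (−1.75 ± 0.06), and 2 higher (0.0473; 0.251), a call lost without library 2 of 0 h (−0.27) or library 2 of 8 h (−0.20). Adjusted over the list alone, only the zinc finger counts changed among these lists, to 299 lower and 41 higher. In the heat shock list, which did not pass (adjusted p = 0.218), 8 of 14 were lower, such as HSPA8 (−2.97 ± 0.07) and DNAJB1 (−3.61 ± 0.09), and 5 higher. The p53, NF-kB, stress response, cholesterol, snoRNA host, well-known lncRNA, histone, erythroid and myeloid lists did not pass either (adjusted p = 0.0597 to 0.92). At 4 h and 8 h, 5625 and 6095 genes were higher and 5168 and 6332 lower. TPM scaling gave 1671 and 3437 higher with 8241 and 8959 lower, and ribosomal protein scaling 251 and 2069 higher with 11422 and 10639 lower. Over the whole time course, a limma F-test called 10052 of 13847 genes in K562 and 13439 of 15942 in HUES9.

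**Figure D2:**
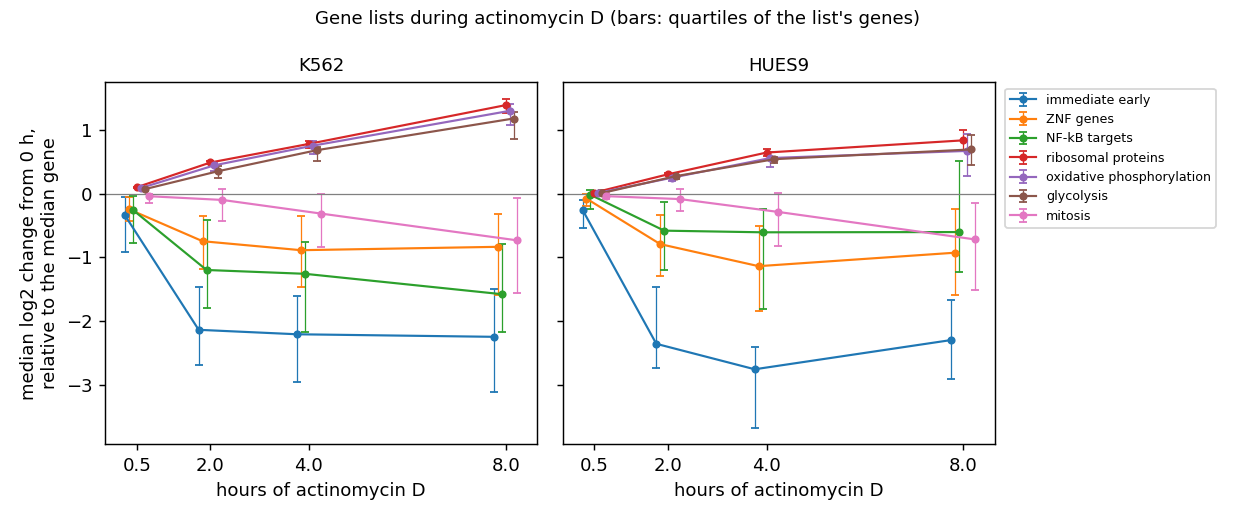
Median log2 change of 7 gene lists relative to the median gene against hours of actinomycin D in K562 and HUES9; bars span the quartiles of the list's genes. Short-lived regulators reach −2.25 in K562 and −2.30 in HUES9 at 8 h and ribosomal protein mRNAs 1.39 and 0.84, rises that shrink to 0.02 in both lines under quantile normalisation. That method leaves highly expressed mRNAs little room to rise. Under TPM scaling at 8 h, ribosomal protein mRNAs changed by 0.61 in K562 and 0.36 in HUES9, and the median gene by −0.75 and −0.46.

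The lncRNAs and mRNAs were compared in each line with 808 lncRNAs and 10786 mRNAs tested in K562 and 820 and 12850 in HUES9. In K562 the median lncRNA changed by 0.11 at 2 h and 0.20 at 8 h, and the median mRNA by 0.10 and 0.03. The differences of the medians (lncRNA minus mRNA) were −0.01, 0.02, 0.05 and 0.17 at 0.5, 2, 4 and 8 h. In HUES9 the differences were −0.02, −0.08, −0.08 and 0.11. None of these 8 differences passed (camera, adjusted p = 0.674 to 0.99). Exact 2-sided permutation tests of the 3 against 3 libraries gave p = 0.7, 0.4, 0.1 and 0.1 in K562 and 0.6, 0.1, 0.1 and 0.1 in HUES9, where 0.1 is the smallest value that design allows. These tests ignored the pairing of libraries by replicate number. Within numbers all 3 differences were positive at 2, 4 and 8 h in K562 (0.013 to 0.0221 at 2 h) and at 8 h in HUES9, and negative at 0.5, 2 and 4 h in HUES9. An exact sign-flip permutation test of the 3 pairs, added after the results were seen, gave p = 0.25, its smallest possible value, for these 7 and 0.5 for K562 at 0.5 h. At 8 h in K562, 323 lncRNAs were higher and 223 lower, or 40.0% and 27.6% of lncRNAs against 40.2% and 40.0% of mRNAs. In HUES9 296 lncRNAs were higher and 243 lower, or 36.1% and 29.6% against 39.0% and 42.6%. At 2 h lncRNAs passed less often than mRNAs in both directions, with 17.6% against 29.2% higher and 13.4% against 23.9% lower in K562 and 10.2% against 24.9% and 16.2% against 23.0% in HUES9. These shares were not tested. The comparison changed when the mRNAs were matched on expression level, for a reason that was not tested. Against mRNAs matched on mean expression the differences at 8 h were 0.53 in K562 and 0.26 in HUES9, and 7 of the 8 differences passed, all but HUES9 at 0.5 h. Matching turned the sign in K562 at 0.5 h (0.05) and in HUES9 at 2 h (0.08) and 4 h (0.14). The K562 lncRNA median stood above all 10000 random matched mRNA lists at each time, as did HUES9 at 8 h. HUES9 stood at percentile 5.36 at 0.5 h and 99.99 at 2 h and 4 h. These lists resample genes within 1 fit and do not measure the spread between libraries. The means used for matching include the treated libraries, so the matching is not independent of the changes. In K562 at 8 h the matched lists had a median of −0.299, against 0.03 for all mRNAs. Ribosomal protein scaling, under which 7 differences passed, and TPM and quantile scaling, under which 3 passed each, also changed calls. These calls come from camera on gene-wise statistics and do not test the sign of the medians. In K562 at 0.5 h on the deposited scale its direction was up, although the median difference was −0.01. Under quantile normalisation the differences in HUES9 at 2 h and 4 h were 0.08 and 0.16, the opposite of the deposited scale.

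Individual lncRNAs covered a wide range at 2 h. In K562 the microRNA host genes MIR142HG (−2.89 ± 0.17) and MIR17HG (−2.83 ± 0.18, from 38.1 ± 4.60 to 5.32 ± 0.964 FPKM, SD, n = 3) fell most among lncRNAs of at least 2 FPKM, ahead of SNHG12 (−1.66 ± 0.09), MRPL20-DT (−1.57 ± 0.14) and EMSLR (−1.46 ± 0.18). MIR663AHG (2.25 ± 0.31), STX16-NPEPL1 (1.69 ± 0.27), RTEL1-TNFRSF6B (1.14 ± 0.28), MIF-AS1 (1.12 ± 0.13) and ALDH1A2-AS1 (1.08 ± 0.20) rose most, although RTEL1-TNFRSF6B and ALDH1A2-AS1 did not pass under ribosomal protein scaling. In HUES9 MIR17HG (−2.38 ± 0.21), SNHG12 (−2.29 ± 0.10), ZNF670-ZNF695 (−2.19 ± 0.12), PHLDA1-AS1 (−2.15 ± 0.17) and MIR222HG (−1.89 ± 0.18) fell most. PTOV1-AS2 (1.48 ± 0.10), SLC25A25-AS1 (1.08 ± 0.15), the imprinted MEG3 (0.94 ± 0.19), LINC01089 (0.94 ± 0.08) and STAG3L5P-PVRIG2P-PILRB (0.88 ± 0.11) rose most. Values of antisense genes and of read-through genes that join neighbours are uncertain, because the labels state no use of strand and such genes overlap others. MALAT1, a nuclear lncRNA, changed by −0.21 ± 0.16 in K562 at 2 h (adjusted p = 0.283, 0.00321 with the replicate block) and rose by 1.27 ± 0.16 at 8 h, although ribosomal protein scaling gave −0.09; in HUES9 it fell by 1.03 ± 0.11 at 2 h and rose by 0.97 ± 0.11 at 8 h (0.22 under ribosomal protein scaling, not past the test). NEAT1 (2.70 ± 0.15) and CRNDE (2.11 ± 0.12) rose and NORAD (−1.80 ± 0.07) and MIR17HG (−3.42 ± 0.21) fell in HUES9 at 8 h.

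**Figure D3:**
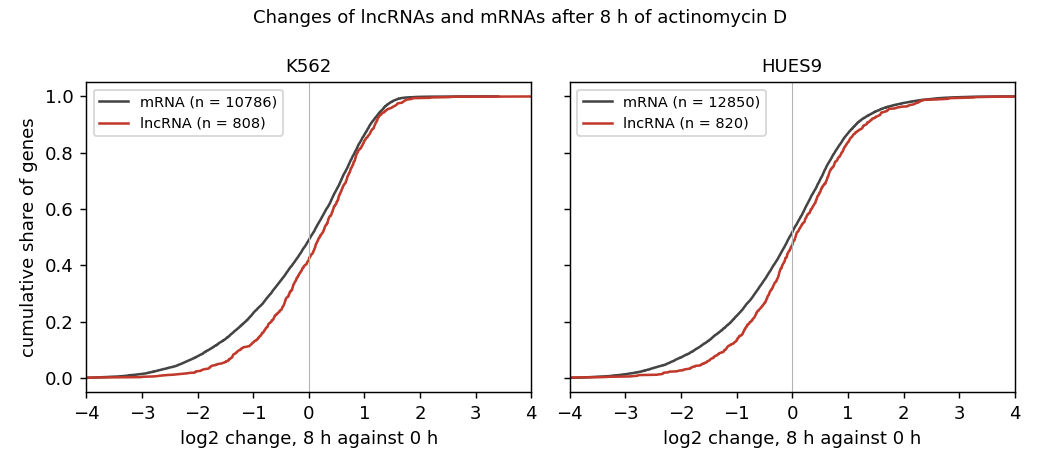
Cumulative share of genes against log2 change from 0 h to 8 h on the deposited scale, for mRNAs (n = 10786 in K562, 12850 in HUES9) and lncRNAs (n = 808 and 820). The lncRNA medians lie 0.17 (K562) and 0.11 (HUES9) above those of mRNAs, and neither difference passed the camera test.

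The difference between the lines in their change from 0 h was tested directly on 12205 genes expressed in both, after removal of each line's median change. At 2 h DAZAP2 fell by 1.17 in HUES9 and rose by 0.44 in K562, a difference of 1.58 ± 0.15 (limma, adjusted p = 3.65e-07). The cyclin CCNL1 (1.4 ± 0.18), ZNF587B (1.39 ± 0.19), the mitochondrial ubiquitin ligase MARCHF5 (1.23 ± 0.14) and the telomere protein TERF2IP (1.16 ± 0.14) also fell in HUES9 and not in K562. DDIT4 (−2.43 ± 0.57), the spindle protein FAM83D (−2.40 ± 0.11), ID1 (−2.19 ± 0.27) and the Integrator subunit INTS5 (−1.69 ± 0.25) fell more in K562. SEMA4B fell by 1.44 in K562 and changed by 0.12 in HUES9 (adjusted p = 0.276), a difference of −1.59 ± 0.24. There were 282 genes with a higher and 569 with a lower change in K562, or 1356 and 1448 with the replicate block. The count of higher genes was 178 without library 1 of K562 2 h, and 608 with no filter on low values. Ribosomal protein mRNAs (median difference 0.19, camera adjusted p = 1.85e-14), oxidative phosphorylation mRNAs (0.19, 1.17e-12) and snoRNA host transcripts (0.15, 0.00186) were higher in K562 relative to HUES9. With an estimated correlation the camera adjusted p was 0.274, 0.274 and 0.75, and quantile normalisation left 0.02, 0.04 and 0.03. Of the members of these lists 6 of 77, 7 of 63 and 4 of 28 were higher and none lower, or 12, 8 and 4 adjusted over the list alone. The snoRNA host difference was 0.08 relative to the median gene without library 2 of K562 0 h.

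At 8 h the lines differed at 2889 genes with a higher and 2970 with a lower change in K562. ITGA5, a fibronectin receptor subunit, fell by 1.69 in K562 and rose by 1.88 in HUES9 (difference −3.65 ± 0.29, limma adjusted p = 4.03e-10). The actin crosslinker FLNC (−3.17 ± 0.27), the collagen-binding receptor ANTXR2 (−3.06 ± 0.21), the proprotein convertase PCSK7 (−2.94 ± 0.23) and the zinc finger factor PLAGL1 (−2.62 ± 0.23) likewise rose in HUES9. YDJC (2.31 ± 0.34), LINC01194 (2.12 ± 0.17), the polymerase epsilon subunit POLE3 (2.00 ± 0.09), the snoRNP protein GAR1 (1.88 ± 0.13) and the mitochondrial ribosomal protein MRPL35 (1.79 ± 0.12) fell in HUES9 and not in K562. Ribosomal protein mRNAs (median difference 0.55, 72 of 77 higher, adjusted p = 5.06e-24; adjusted p = 0.16 with an estimated correlation) and oxidative phosphorylation mRNAs (0.65, 60 of 63 higher, 5.06e-24, a call that held with an estimated correlation) rose more in K562, but 0.01 and 0.24 remained under quantile normalisation. Glycolytic (0.47, 12 of 17 higher and 2 lower, camera adjusted p = 0.00495), DNA replication (0.40, 20 of 30 higher, 3.09e-06) and heat shock mRNAs (0.43, 9 of 14 higher and 2 lower, 0.00747) were also higher in K562. So were snoRNA host transcripts (0.36, 13 of 28 higher and 1 lower, 0.00495). With an estimated correlation the camera adjusted p of these 4 lists was 0.38, 0.271, 0.296 and 0.685. Under quantile normalisation the glycolytic, heat shock and snoRNA host differences were 0.21, 0.17 and 0.10 and that of NF-kB targets −0.13, none of them past the test. NF-kB targets were lower, by −0.41 with 5 of 11 lower (0.0381; adjusted p = 0.298 with an estimated correlation and 0.0538 with the replicate block, 0.000247 to 0.298 over all alternatives). Adjusted over the list alone, the ribosomal protein and oxidative phosphorylation counts were 73 and 61 and the others were the same. Relative to the median gene, the NF-kB difference was −0.61 without library 0 of K562 8 h, and the snoRNA host difference 0.20 without library 1 of K562 8 h. Across genes, the changes of the lines correlated with Pearson's r of 0.82 at both times, where genes are not independent replicates. At 8 h 3848 genes were lower in both lines, against 1912 for independent lists, 3617 were higher in both, against 1905, and 619 went opposite ways. The lncRNA minus mRNA difference was higher in K562 by 0.05 at 2 h (camera, adjusted p = 0.0472) and lower by 0.00 at 8 h (−0.000889, adjusted p = 0.958). These p-values were adjusted over these times only, and no alternative was run for this comparison.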

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

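The differences below between the lines' changes, K562 minus HUES9, come from the fixed design. None of the tests behind them was chosen after the result was seen. Differences were found for 282 genes higher and 569 lower in K562 at 2 h and for 2889 and 2970 at 8 h. The lists that passed at 2 h were ribosomal proteins (0.187), oxidative phosphorylation (0.191) and snoRNA hosts (0.149), and all 3 calls were lost with an estimated correlation (adjusted p = 0.274, 0.274 and 0.75). At 8 h they were ribosomal proteins (0.551), oxidative phosphorylation (0.645), glycolysis (0.469), DNA replication (0.398), snoRNA hosts (0.364), heat shock (0.428) and NF-kB targets (−0.407). With an estimated correlation only the call for oxidative phosphorylation held (adjusted p = 0.0396, against 0.16 to 0.685 for the others). The lncRNA minus mRNA difference was 0.0549 at 2 h (camera, adjusted p = 0.0472), and no alternative was run for it. Genes at 2 h were DAZAP2 (1.58), CCNL1 (1.4), ZNF587B (1.39), MARCHF5 (1.23), TERF2IP (1.16), DDIT4 (−2.43), FAM83D (−2.40), ID1 (−2.19), INTS5 (−1.69), SEMA4B (−1.59), MYC (−1.36), SNHG12 (0.604) and MALAT1 (0.796).

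Genes that differed at 8 h, tested in the same design, were YDJC (2.31), LINC01194 (2.12), POLE3 (2.00), GAR1 (1.88), MRPL35 (1.79), ITGA5 (−3.65), FLNC (−3.17), ANTXR2 (−3.06), PCSK7 (−2.94) and PLAGL1 (−2.62). Reference genes and list members that differed upward in K562 were PGK1 (0.566), HSPA8 (1.37), GAPDH (0.648), UQCR11 (0.357), CCNB1 (0.711), H2AC6 (1.15), H2AC25 (1.78), RPL37A (0.392), HSPA1A (0.334) and ATP5MF (0.306). Those lower in K562 were PKM (−0.819), XBP1 (−0.286), DNAJB1 (−0.624), MYC (−1.19), PPM1D (−0.767), ZNF622 (−0.702), MT-ND3 (−1.35), MT-RNR1 (−0.730) and NORAD (−0.662).

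The splits of the libraries were set in the design and not chosen after the result. Each of the 8 time comparisons has 10 splits of its 6 libraries into 3 and 3, and only 1 split, the real one, reached its own number of calls. The real totals were 69, 6694, 9045 and 10573 in K562 and 29, 7007, 10793 and 12427 in HUES9 at 0.5, 2, 4 and 8 h. The highest other split had 0 calls, or 1 in HUES9 at 0.5 h, in a split that keeps a pair of same-numbered libraries together. With 10 splits no share under 0.05 is possible. The same holds for the line difference, where 3 and 3 paired changes gave 2428 calls at 2 h and 6618 at 8 h and the highest other split 0. For any change over time, 1 of 100 regroupings within replicate numbers, the real one, reached 10052 calls in K562, against a highest other of 6075, and 1 of 100 reached 13439 in HUES9, against 11015, so a random grouping was excluded there. Regroupings that ignore the numbers had a median of 0 calls in both lines over 50, with a highest of 4783 in K562 and 1 in HUES9.

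All tests of the next pattern were written after the result was seen. MT-RNR1, MT-RNR2, 7SK, SNORD3A and SCARNA9 rose at 8 h with a median of 3.96 in K562 (5 RNAs) and 4.22 in HUES9 (4 RNAs). With ribosomal protein scaling the lower of the lines' medians was still 2.60, so that scaling did not remove the rise. This K562 median is the value of 7SK alone, which had a wide spread (3.96 ± 0.95 on the deposited scale). The RNAs had been chosen for their rise, so the authors' scaling was not excluded. Stable RNAs filling the share that decayed mRNAs left cannot be told apart from other causes: the medians stood at least 1.89 above the 99th percentile of mRNAs of at least 5 FPKM, but the RNAs had been chosen for their rise. The carry-over of RNAs without a poly(A) tail through the selection cannot be told apart from stable RNAs: other small noncoding RNAs had medians of 1.196 in K562 (7 RNAs) and 1.08 in HUES9 (9 RNAs), against 1.461 and 0.825 for ribosomal protein mRNAs and upper quartiles of mRNAs of 0.70 and 0.61. With the 7SL pseudogenes, first counted and later left out, these medians were 0.54 over 20, below the upper quartile in K562, and 1.05 over 12.

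For the last pattern the differentiated-cell prediction was written before its lists were tested, but after the rise was seen, and the mesenchymal and cardiac lists were written after ACTA2, COL1A1, COL3A1, MYL4 and NPPB had been seen. In HUES9, 156 mRNAs of at least 5 FPKM rose at least 4-fold at 8 h. Had the authors' scaling been the whole cause, ribosomal protein or TPM scaling was predicted to bring the median to 0 or below. The lower median was 1.65, so these scalings did not remove the rise. The mRNAs had been chosen for that rise on the deposited scale, so the authors' scaling was not excluded. Stable mRNAs filling the vacated share cannot be told apart from other causes: from 4 h to 8 h these mRNAs rose by 1.51 more than the ribosomal protein mRNAs, but they had been chosen for their level at 8 h. A larger share of differentiated cells at 8 h stays open as well: the endoderm and liver list had a median of 1.07 (7 of 17 measured) and neural genes 1.14 (13 of 16), or 0.43 each under ribosomal protein scaling, mesenchymal genes 2.39 (23 of 24) and cardiac genes 2.57 (8 of 12), while only 3 trophoblast genes were measured (−1.63). No other biological cause was tested.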

How the results depend on the processing

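Groups of 3 libraries tie p-values to the spread between them, FPKM carry no fragment counts, and no spike-in fixes the absolute scale, so directions depend on the scaling. Values of lists and genes below are relative to the median gene, whose line difference was 0.018 at 2 h and −0.011 at 8 h, and counts are of genes. Of 277 called results for named genes, 208 changed under no alternative. Of 47 called list results, 12 changed under no alternative and 10 more changed only with an estimated correlation. The 8 class differences were not called, and each changed under at least 1 alternative. A class call below is that of camera on gene-wise statistics. The median difference printed beside it was not itself tested. A pseudocount of 0.01 FPKM, lncRNAs with a LINC symbol only, and the slope per hour instead of contrasts changed no required result. The cause of the changes below was not tested. By construction, though, TPM and ribosomal protein scaling shift all genes of a library, and quantile normalisation gives every library the same values rank by rank.

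TPM scaling gave K562 0.5 h 235 lower, K562 2 h 529 higher and 5803 lower, K562 4 h 996 higher and 7522 lower, K562 8 h 1299 higher and 9051 lower, HUES9 2 h 702 higher and 5581 lower, HUES9 4 h 1671 higher and 8241 lower, HUES9 8 h 3437 higher. With TPM the lncRNA minus mRNA difference passed at 0.029 in K562 2 h, 0.070 in K562 4 h, 0.21 in K562 8 h. Lost with TPM were the list calls in K562 8 h stress response −1.97. Gained with TPM were calls in K562 2 h mitosis −0.11, in K562 8 h mitochondrially encoded mRNAs −0.32, erythroid 0.58, in HUES9 2 h mitosis −0.091, snoRNA hosts −0.10.

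Quantile normalisation made the lncRNA minus mRNA difference pass with 0.18 in K562 2 h, 0.27 in K562 4 h, 0.43 in K562 8 h. Lost with quantiles were the list calls in K562 8 h glycolysis 0.086, well-known lncRNAs 0.38, in HUES9 2 h oxidative phosphorylation 0.00082, in HUES9 8 h ribosomal proteins 0.016, oxidative phosphorylation 0.020, in line difference 2 h ribosomal proteins 0.015, snoRNA hosts 0.028, in line difference 8 h ribosomal proteins 0.0081, glycolysis 0.21, NF-kB targets −0.13, snoRNA hosts 0.10, heat shock 0.17. Gained with quantiles were calls in K562 2 h mitochondrially encoded mRNAs −0.39, mitosis −0.29, snoRNA hosts −0.30, heat shock −0.30, in K562 8 h mitochondrially encoded mRNAs −1.44, DNA replication −0.28, heat shock −0.40, cholesterol −0.51, in HUES9 2 h mitochondrially encoded mRNAs −0.39, pluripotency −0.29, mitosis −0.21, snoRNA hosts −0.33, heat shock −0.22, cholesterol −0.22, in HUES9 8 h snoRNA hosts −0.61, stress response −1.23, heat shock −0.77, in line difference 2 h mitochondrially encoded mRNAs −0.068, p53 targets 0.20, erythroid −0.22, heat shock −0.13, in line difference 8 h mitochondrially encoded mRNAs −0.34, erythroid −0.91. Called lists reversed in sign by quantiles were in K562 2 h ribosomal proteins −0.017, glycolysis −0.025, in HUES9 2 h ribosomal proteins −0.041, glycolysis −0.036, in HUES9 8 h glycolysis −0.071. Named genes whose change relative to the median gene turned sign with quantiles were in K562 0.5 h MT-CO2 −0.010, in K562 2 h HBE1 −0.013, HBG1 −0.047, HBG2 −0.016, GAPDH −0.046, ACTB −0.17, in K562 8 h ATP5F1B −0.16, UQCRH −0.021, MT-CO1 −0.53, HK1 −0.19, ENO1 −0.10, BAX −0.083, MCM7 −0.29, CYTOR −0.14, HSP90AB1 −0.39, H2BC12 −0.072, H2AC6 −0.095, HBG1 −0.063, GAPDH −0.032, ACTB −0.45, in HUES9 2 h GAPDH −0.11, ACTB −0.090, in HUES9 8 h PGK1 −0.071, GAPDH −0.21. Gene calls test the change before that subtraction, where some of these genes, such as HBE1 and HBG2 in K562 at 2 h, stayed slightly positive.

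Ribosomal protein scaling gave K562 0.5 h 6 higher and 545 lower, K562 2 h 63 higher and 9023 lower, K562 4 h 101 higher and 10115 lower, K562 8 h 134 higher and 11622 lower, HUES9 2 h 229 higher and 7860 lower, HUES9 4 h 251 higher and 11422 lower, HUES9 8 h 2069 higher and 10639 lower. With ribosomal protein scaling the lncRNA minus mRNA difference passed at −0.0073 in K562 0.5 h, 0.039 in K562 2 h, 0.088 in K562 4 h, 0.23 in K562 8 h, −0.061 in HUES9 2 h, −0.035 in HUES9 4 h, 0.13 in HUES9 8 h. Lost with ribosomal protein scaling were the list calls in K562 2 h p53 targets −0.34, in K562 8 h p53 targets −0.97, NF-kB targets −1.59, well-known lncRNAs 0.71, stress response −1.97, in HUES9 8 h glycolysis 0.67, in line difference 8 h NF-kB targets −0.38. Gained with ribosomal protein scaling were calls in K562 2 h mitosis −0.11, snoRNA hosts 0.040, heat shock −0.048, in K562 8 h erythroid 0.56, DNA replication 0.0094, in HUES9 2 h mitosis −0.095, snoRNA hosts −0.10, histones 0.22, in HUES9 8 h stress response −1.44.

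A demand for at least 2-fold changes gave K562 0.5 h 2 higher and 18 lower, K562 2 h 117 higher and 1033 lower, K562 4 h 350 higher and 1936 lower, K562 8 h 1937 higher and 2911 lower, HUES9 0.5 h 2 higher and 2 lower, HUES9 2 h 108 higher and 1063 lower, HUES9 4 h 317 higher and 2480 lower, HUES9 8 h 2167 higher and 3280 lower.

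Centring of each library on its median gene, added after the data were seen, gave K562 0.5 h 31 lower, K562 2 h 6027 higher, HUES9 2 h 6830 higher, HUES9 4 h 8616 higher. Lost with centring were the list calls in K562 2 h histones 0.19, in K562 8 h well-known lncRNAs 0.70, in HUES9 8 h mitochondrially encoded mRNAs −0.23, DNA replication −0.54. Gained with centring were calls in K562 2 h DNA replication 0.091, in HUES9 2 h pluripotency −0.090, in HUES9 8 h stress response −1.42.

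An estimated correlation removed list calls in K562 2 h glycolysis 0.35, p53 targets −0.35, stress response −0.82, histones 0.19, in K562 8 h short-lived regulators −2.25, ribosomal proteins 1.39, glycolysis 1.18, p53 targets −0.95, NF-kB targets −1.58, mitosis −0.74, well-known lncRNAs 0.70, stress response −1.95, histones 0.74, in HUES9 2 h ribosomal proteins 0.30, oxidative phosphorylation 0.25, glycolysis 0.27, p53 targets −0.50, NF-kB targets −0.58, in HUES9 8 h short-lived regulators −2.30, ribosomal proteins 0.84, oxidative phosphorylation 0.67, mitochondrially encoded mRNAs −0.23, glycolysis 0.69, mitosis −0.72, DNA replication −0.54, in line difference 2 h ribosomal proteins 0.17, oxidative phosphorylation 0.17, snoRNA hosts 0.13, in line difference 8 h ribosomal proteins 0.56, glycolysis 0.48, NF-kB targets −0.40, DNA replication 0.41, snoRNA hosts 0.38, heat shock 0.44.

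Comparison with mRNAs matched on mean expression made the lncRNA minus mRNA difference pass with 0.046 in K562 0.5 h, 0.22 in K562 2 h, 0.35 in K562 4 h, 0.53 in K562 8 h, 0.077 in HUES9 2 h, 0.14 in HUES9 4 h, 0.26 in HUES9 8 h.

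A filter at a mean of 2 FPKM gave HUES9 0.5 h 9 lower. Lost with this filter were the list calls in K562 8 h well-known lncRNAs 0.83, stress response −1.98, in HUES9 2 h NF-kB targets −0.20, in HUES9 8 h mitochondrially encoded mRNAs −0.23, in line difference 8 h NF-kB targets −0.51. Gained with this filter were calls in line difference 2 h well-known lncRNAs 0.27.

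No filter on low values gave line difference 2 h 608 higher, line difference 8 h 4649 higher. Gained with no filter were calls in K562 2 h erythroid 0.27, DNA replication 0.19, in K562 8 h erythroid 0.68, in HUES9 2 h pluripotency 0.019, germ layers −0.64, in HUES9 8 h p53 targets −0.52, stress response −1.44, heat shock −0.38, in line difference 2 h NF-kB targets −0.28, in line difference 8 h pluripotency 0.62, mitosis 0.25, histones 0.31.

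Use of only K562 libraries 0 and 2, added after the data were seen, gave K562 0.5 h 17 lower. Lost with these libraries were the list calls in K562 2 h histones 0.21, in K562 8 h well-known lncRNAs 0.81, in line difference 8 h NF-kB targets −0.44.

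A fit of only the 6 libraries compared gave K562 0.5 h 3 higher and 30 lower, HUES9 0.5 h 1 higher and 3 lower.

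A fit of only the libraries compared removed list calls in line difference 8 h NF-kB targets −0.40.

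A pseudocount of 1 FPKM gave K562 0.5 h 186 lower, HUES9 0.5 h 34 lower. Gained with pseudocount 1 were calls in K562 2 h DNA replication 0.11, in HUES9 8 h stress response −1.29, in line difference 8 h histones 0.34.

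The replicate number as a block gave K562 0.5 h 1297 higher and 650 lower, HUES9 0.5 h 51 higher and 38 lower, line difference 2 h 1356 higher and 1448 lower. Lost with the block were the list calls in K562 2 h histones 0.19, in K562 8 h stress response −1.95, in line difference 8 h NF-kB targets −0.40. With the block 6 named genes gained a call: in K562 at 2 h HBA1 (0.33), HBA2 (0.36), GATA1 (−0.34) and MALAT1 (−0.31), in K562 at 8 h DNMT3B (−0.17) and in HUES9 at 8 h POU5F1 (0.14). The block changed no other call of a named gene, or of a list at 2 h or 8 h.

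Leaving out 1 library at a time left K562 at 0.5 h with 2 to 5 higher and 11 to 20 lower genes, HUES9 at 0.5 h with 4 to 13 higher and 0 to 4 lower, and the line difference at 2 h with 178 to 310 higher. List medians whose call changed ranged, in K562, from 0.081 to 0.11 for DNA replication at 2 h and from 0.65 to 0.79 for well-known lncRNAs at 8 h. In HUES9 they ranged from −0.099 to −0.049 for snoRNA hosts at 2 h, from −1.47 to −1.34 for the stress response at 8 h and from −0.27 to −0.20 for mitochondrially encoded mRNAs at 8 h. The HUES9 class difference at 0.5 h ranged from −0.043 to −0.013. For the line difference, p53 targets at 2 h ranged from 0.032 to 0.18, pluripotency at 2 h from −0.31 to −0.18, well-known lncRNAs at 2 h from 0.15 to 0.24, NF-kB targets at 8 h from −0.61 to −0.32 and histones at 8 h from 0.16 to 0.48.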

Other observations

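Further lists were tested after the results of the design lists had been seen, and their p-values are adjusted only among themselves. Chromatin modifiers and remodellers fell in both lines at 8 h, by 1.39 in K562 and 1.47 in HUES9 relative to the median gene. Of these genes 25 of 29 were lower in each line, and 3 in K562 and 2 in HUES9 higher (camera, adjusted p = 0.111 and 0.209 with an estimated correlation). A list of F-box and BTB family genes, named as ubiquitin ligases, was written after FBXO5 was seen. It kept FBXO5 as a member (−3.83 in K562 and −3.97 in HUES9 on the deposited scale), so its test is not independent of that gene. The list fell by 1.16 in K562 (20 of 26 lower and 2 higher, camera adjusted p = 0.111 with an estimated correlation). In HUES9 it fell by 1.14 (23 of 26 lower and 2 higher, 0.047 with an estimated correlation).

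Proteasome mRNAs rose in K562 at 8 h by 0.82, with 24 of 30 higher and 2 lower (camera, adjusted p = 2.48e-06; 0.111 with an estimated correlation), while the list did not pass in HUES9 at 8 h (0.19, 17 higher and 8 lower, adjusted p = 0.43). Aminoacyl-tRNA synthetases rose in K562 by 0.53, with 15 of 20 higher and 3 lower (camera, adjusted p = 0.00242, or 0.161 with an estimated correlation). In HUES9 9 of 20 synthetases were higher and 4 lower (0.15, adjusted p = 0.43). General splicing and SR proteins rose in K562 by 0.52, with 20 of 27 higher (0.00158, or 0.111 with an estimated correlation). The 3 lower in K562 were SF3B3, SRSF4 (−1.11) and SRSF5 (−0.58). In HUES9 15 of 27 were higher and 6 lower (0.20, adjusted p = 0.236). In HUES9 all 3 lists passed at 2 h, with 26, 14 and 20 members higher (adjusted p = 3.25e-06, 0.000474 and 5.70e-06; 0.343, 0.425 and 0.101 with an estimated correlation), and at 4 h, with 23, 15 and 21 higher (3.89e-05, 0.00363 and 0.000101; 0.307, 0.366 and 0.181 with an estimated correlation). The difference between the lines was not tested for these lists. Without subtraction of the median gene and under ribosomal protein scaling, all 3 medians in K562 were negative (proteasome −0.47, synthetases −0.76, splicing −0.77).

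Abundant members of the 156 HUES9 mRNAs that rose at least 4-fold at 8 h included TAGLN (236 to 2230 FPKM), SPARC (294 to 1540), FN1 (77.7 to 580), CRABP1 (264 to 1220) and ACTC1 (47.1 to 231). Of these mRNAs 76 were tested in K562, where their median change was 1.07 and 2 rose 4-fold. The mesenchymal list rose in K562 by 0.65 relative to the median gene, with 10 of 11 measured genes higher (adjusted p = 0.0032; 0.0684 with an estimated correlation). Under ribosomal protein scaling its median change was −0.61 in K562, against 1.64 in HUES9.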
